A study of Arabidopsis thaliana with 4 samples.

How the data were processed

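Shoot apices carrying leaf primordia were taken from Arabidopsis thaliana plants grown for 14 days under 16 h of light and 8 h of darkness. Plants were either wild type (the Col-0 accession) or as2-1, a mutant of ASYMMETRIC LEAVES2 (AS2), which encodes a nuclear protein that acts in leaf development. Both genotypes grew on agar medium containing either the solvent DMSO or 10H-CPT, a form of camptothecin with a hydroxyl group at position 10. Camptothecin inhibits DNA topoisomerase 1 by trapping it on nicked DNA. The dose of 10H-CPT is not given in the sources used here. Per the labels' protocols, total RNA was purified on RNeasy columns and biotinylated cRNA was hybridised to Affymetrix arrays. The 4 groups are wild type on DMSO, wild type on 10H-CPT, as2-1 on DMSO and as2-1 on 10H-CPT, with 1 array each. There are no replicates, and the number of arrays limits the precision of every value.

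The deposited values are signal intensities on a linear scale, 1 per probe set, made with MAS5 per the submitters' processing notes. The version of MAS5 and its scaling target are not given in the sources used here. MAS5 subtracts mismatch signals before it summarises the probes of a set, so low values are noisy on a ratio scale. Each array held 22746 probe sets, and the 2% trimmed means of the 4 arrays lay between 198.3 and 198.5. This is within the 5% tolerance set before the data were examined, so the deposited scaling was kept. Median signals were 86.8 for wild type on DMSO, 86.0 for wild type on 10H-CPT, 88.3 for as2-1 on DMSO and 87.5 for as2-1 on 10H-CPT. Detection calls and control probe sets were not analysed here, so a planned check of RNA quality from control genes was not run.

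Values under the 40th percentile of all signals, 46.6, were raised to that floor before log2 transformation. A ratio with 1 array at the floor is a bound and is written as "at least", and a ratio with both arrays at the floor was left out of the counts. List medians took each member above the floor in at least 1 array, so a ratio with both arrays at the floor entered them as 0. A list median of 0 can therefore come from floored values and need not mean that no change was measured. Between 13590 and 13709 probe sets per array lay above the floor, and 12716 did so in all 4 arrays. Single comparisons are log2 ratios of 2 arrays without a test, summarised by counts of probe sets at or over 2-fold. The difference of the 10H-CPT ratio between genotypes uses all 4 arrays and also has no test. Mean effects of 10H-CPT and of as2-1 were tested with limma 3.58.1 in R 4.3.3, in an additive model of genotype and medium fitted with lmFit and eBayes. This fit took the 13924 probe sets above the floor in at least 2 arrays, and a Benjamini-Hochberg adjusted p under 0.05 made a call. Its 1 residual degree of freedom holds any interaction of genotype and medium as well as array noise, and its prior added 5.32 degrees of freedom. Nothing in the labels says how many plants or cultures stand behind an array, so p-values do not measure the spread between plants or cultures. They set each effect against the departure of these arrays from the additive model and a prior variance taken from all probe sets tested. Other calculations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots used matplotlib 3.10.9.

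Of the probe sets, 13513 have 1 gene in the annotation used here, 503 have several and 8730 are unnamed in it. Of the 13513, 13436 matched a gene table of assembly TAIR10.1, which was used for names and gene order only. AS2 itself, the class 1 KNOX genes and most other genes on the planned lists are not named in the annotation used here, so the planned check of the AS2 level was not run. For a gene with several probe sets the one with the highest mean signal was used. Named genes were chosen by a rule fixed before the data were examined. It takes the 10 highest and 10 lowest genes at or over 2-fold in both genotypes for 10H-CPT, or on both media for as2-1, ranked by the smaller ratio. It also takes the 5 highest and 5 lowest of each single comparison and of the genotype difference, the 3 largest bounds each way, and members of the gene lists. Of 305 members of 25 lists fixed before the data were examined, 49 have a named probe set, 33 of these were above the floor in at least 1 array, and 4 lists kept no named member. Because this left few genes per list, 22 further lists were written once the annotation had been seen and before any value of their members was looked at. A last set of 7 lists was written after the strongest genes had been seen, from background knowledge, and appears only in the closing section. List medians are given with their percentile among 10000 random gene lists of the same size, matched on mean log2 signal in 20 bins, for lists with at least 5 measured members. Such a percentile describes these arrays only. Limma p-values were also adjusted over each list alone, which for a list with few tested members is little or no adjustment.

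The limma step was tested on simulated data for the mean 10H-CPT effect, with noise drawn from the fitted prior. Over 13872 simulated probe sets it recovered 11 of 98 with a 2-fold change and 84 of 100 with a 4-fold change, with 3 false calls among 98. The list percentile was tested on 25 members shifted by 0.4 in the wild type 10H-CPT ratio, over 13924 probe sets, and placed their median at percentile 100. Of 100 simulated lists without a shift, 7 fell below percentile 2.5 or above percentile 97.5. Simulated noise was drawn independently for each probe set, so this does not cover lists whose members vary together between arrays. Alternatives were no floor, a floor at the 60th percentile, the floor as a pseudocount, quantile, median and cyclic loess scaling, and removal of the 1061 probe sets ending in _s_at or _x_at. Counts were also taken at 3-fold and 1.5-fold, list medians over all probe sets of a gene, and limma without its filter or with an intensity trend.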

Results

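Signals of 22746 probe sets were compared between shoot apices of wild type and as2-1 plants grown on DMSO or on 10H-CPT, with 1 array in each of the 4 groups. Correlations of log2 signals between arrays lay between 0.953 and 0.984 across probe sets, which are not independent replicates. The closest pair was wild type and as2-1 on DMSO, and the most distant was wild type on DMSO and as2-1 on 10H-CPT. The design asks which genes respond to loss of AS2 function, which respond to an inhibitor of topoisomerase 1, and how far both sets of genes overlap.

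On 10H-CPT, transcripts of DFR, BCAT4 and genes of the DNA damage response were higher in both genotypes, and transcripts of GI, FHL and ARL were lower. Of named genes AT5G20790 had the lowest mean ratio, with signals of 762 on DMSO and 43.9 on 10H-CPT in wild type, and of 525 and 7.90 in as2-1. Both values on 10H-CPT lay under the floor, so the gene was at least 16.3-fold lower in wild type and at least 11.3-fold lower in as2-1. In wild type alone AT5G05250 had the highest ratio of named genes and went from 30.5, under the floor, to 1115 in wild type, at least 23.9-fold, and from 238 to 1111 in as2-1. The limma test of the mean 10H-CPT effect over both genotypes called 128 probe sets higher and 187 lower at adjusted p under 0.05, of which 132 have 1 named gene. With the floor at the 60th percentile it called 93 higher and 92 lower, so the excess of lower calls was absent there. At an unadjusted p under 0.05 limma gave 1100 higher and 1258 lower. Without the floor limma called 0 either way (899 higher and 1095 lower unadjusted), and 0 also with all probe sets tested (979 and 1216).

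In single comparisons, 218 probe sets were at or over 2-fold higher and 296 lower on 10H-CPT in wild type, and 422 higher and 327 lower in as2-1. Without the floor lower probe sets outnumbered higher ones in as2-1, 2152 to 1924. Of the named genes above the floor in all arrays, 35 were at or over 2-fold higher and 29 lower in both genotypes. Among the 10 highest of these, AT3G23570 rose by a mean log2 ratio of 1.88 (SE 0.17, limma adjusted p = 0.0128), from 311 to 1187 in wild type and from 397 to 1399 in as2-1. AT5G67150 rose by 1.73 (SE 0.17, limma adjusted p = 0.0144). DFR (AT5G42800), the dihydroflavonol reductase of anthocyanin synthesis, rose by 2.26 (SE 0.34, limma adjusted p = 0.0314), from 61.6 to 176 in wild type and from 87.2 to 698 in as2-1. BCAT4 (AT3G19710), an aminotransferase of methionine chain elongation in glucosinolate synthesis, had the largest wild type ratio of named genes above the floor in both arrays, with 401 on DMSO and 6468 on 10H-CPT. In as2-1 BCAT4 stood at 2212 and 6324, and its mean effect did not pass (limma adjusted p = 0.0587). The remaining 6 of the 10, AT1G03820, AT3G19030, AT1G21440, AT2G16630, AT2G18600 and AT5G67460, rose by mean log2 ratios between 1.52 and 1.98, all with limma adjusted p of 0.0246 or less. Bounds were large for AT1G47400, at least 19.9-fold higher in wild type, and for AT1G73600, at least 7.02-fold higher in wild type, with a ratio of 5.22-fold in as2-1.

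**Figure D1:**
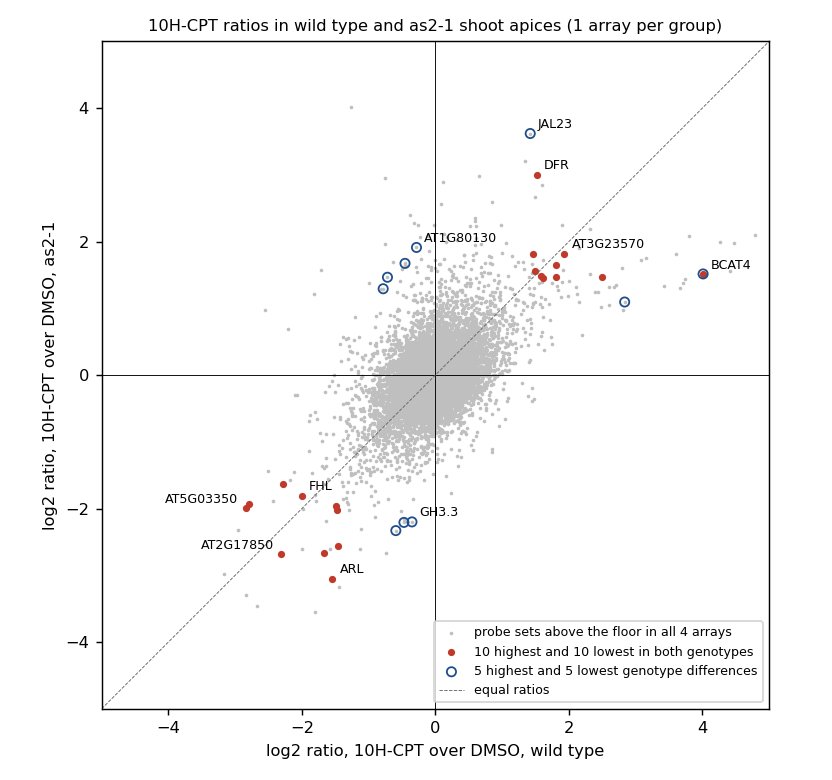
Log2 ratios of 10H-CPT over DMSO in wild type (x axis) and in as2-1 (y axis). Each grey point is a probe set above the floor in all 4 arrays. Filled points are the 10 highest and 10 lowest named genes in both genotypes, and open circles are the 5 highest and 5 lowest named genotype differences. Both sets were drawn from named genes above the floor in all 4 arrays. BCAT4 lies at 4.01 and 1.52, below the dashed line of equal ratios, and JAL23 lies above it at 1.42 and 3.62.

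All 10 of the lowest genes fell on 10H-CPT by the limma test. AT2G17850 had a mean log2 ratio of -2.497 (SE 0.18, limma adjusted p = 0.0111), from 367 to 74.1 in wild type and from 404 to 62.8 in as2-1. AT5G03350 went from 1235 to 172 in wild type, a mean log2 ratio of -2.42 (SE 0.24, limma adjusted p = 0.0144). GI (AT1G22770), a component of the circadian clock, had a mean log2 ratio of -2.17 (SE 0.26, limma adjusted p = 0.02), and FHL (AT5G02200), which acts in phytochrome A signalling, had -1.91 (SE 0.17, limma adjusted p = 0.0128). ARL (AT2G44080), a regulator of organ size, went from 507 to 174 in wild type and from 924 to 112 in as2-1. AT1G19960, AT1G13750, AT3G03270, AT1G03020 and AT4G27450 had mean log2 ratios of -2.36, -1.96, -1.73, -1.74 and -2.01. AT1G33055 had -3.03 in wild type, the lowest there of named genes above the floor in both arrays, and AT4G10270 had -3.17 in as2-1. OSM34 (AT4G11650), an osmotin-like protein, and AT5G55450 were at least 5.71-fold and at least 5.86-fold lower in wild type. In as2-1, AT4G33560 was at least 6.89-fold lower. CHIL (AT5G05270), a chalcone isomerase-like protein, was 6.56-fold higher in as2-1, and JAL23 (AT2G39330), a jacalin-related lectin, was 12.3-fold higher there.

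Genes of the DNA damage response were higher on 10H-CPT in both genotypes. The extended list of 10 measured members, fixed, like all extended lists and gene families here, after the annotation had been seen but before their values, had a median log2 ratio of 0.67 in wild type and 0.76 in as2-1, each at percentile 100 of matched random lists. With the floor at the 60th percentile the medians were 0.15 and 0.49. Of 9 tested members 3 rose and 6 did not pass limma, and 6 rose when p was adjusted over the list alone. AT2G18600, on the list fixed before the data were examined, rose by 1.63 (SE 0.18, limma adjusted p = 0.0175). ATMND1 (AT4G29170), which acts in homologous recombination, was higher with log2 ratios of 0.899 and 0.76 without passing (limma adjusted p = 0.0693). All 3 measured members of the list fixed first passed when adjusted over the list alone, against 1 over all probe sets tested.

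Genes of the G2 and M phases were higher on 10H-CPT in wild type, where 21 of 25 measured members of the extended list had ratios above 0. Their median was 0.47 in wild type, at percentile 100, and 0.072 in as2-1, at percentile 87.1. The Aurora kinase genes AUR1 (AT4G32830) and AUR2 (AT2G25880) had log2 ratios of 0.63 and 0.97 in wild type and of 0.26 and 0.501 in as2-1. Of 24 tested members of the extended list none passed limma, nor when adjusted over the list alone. Both Aurora genes passed over their fixed list alone, which had 2 tested members. The 4 replication genes PRL (AT4G02060), ICU2 (AT5G67100), POLA3 (AT5G41880) and PSF2 (AT3G12530) had medians of 0.696 in wild type and 0.39 in as2-1, without a limma call. PRL and ICU2, the members of the fixed replication list, both passed when adjusted over the list alone. Histone genes, 8 measured, had a median of 0.31 in wild type and 0.050 in as2-1, and HTB2 (AT5G22880) went from 595 to 1069 in wild type.

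Genes of cytosolic ribosomal proteins, 95 measured, were slightly higher on 10H-CPT in wild type, with a median of 0.22 and 84 members above 0. In as2-1 the median was -0.15, with 74 members below 0, beside a median of -0.11 for matched random lists, which puts it at percentile 23.5. With quantile scaling the as2-1 median was -0.063 and with loess scaling -0.034, beside random medians of -0.0686 and -0.0282. None of the 95 passed limma for the mean effect. The 5 members of the fixed list of nucleolus and ribosome biogenesis had medians of 0.21 and -0.102, and PRH75 (AT5G62190), an RNA helicase, had -0.23 and -0.35. Mitochondria-encoded transcripts, 10 measured, had medians of -0.21 in wild type and -0.78 in as2-1, the latter at percentile 0, and cox1 had -0.39 and -0.96. Random lists were drawn gene by gene, so this percentile does not allow for members that vary together. None of these 10 passed limma for the mean 10H-CPT effect, nor when adjusted over the list alone. Chloroplast-encoded transcripts, 50 measured, had medians of 0.13 and -0.090. Nuclear genes of photosynthesis, 9 measured, had medians of -0.065 and 0.17, and RCA (AT2G39730), the Rubisco activase, had 0.17 and 0.68.

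**Figure D2:**
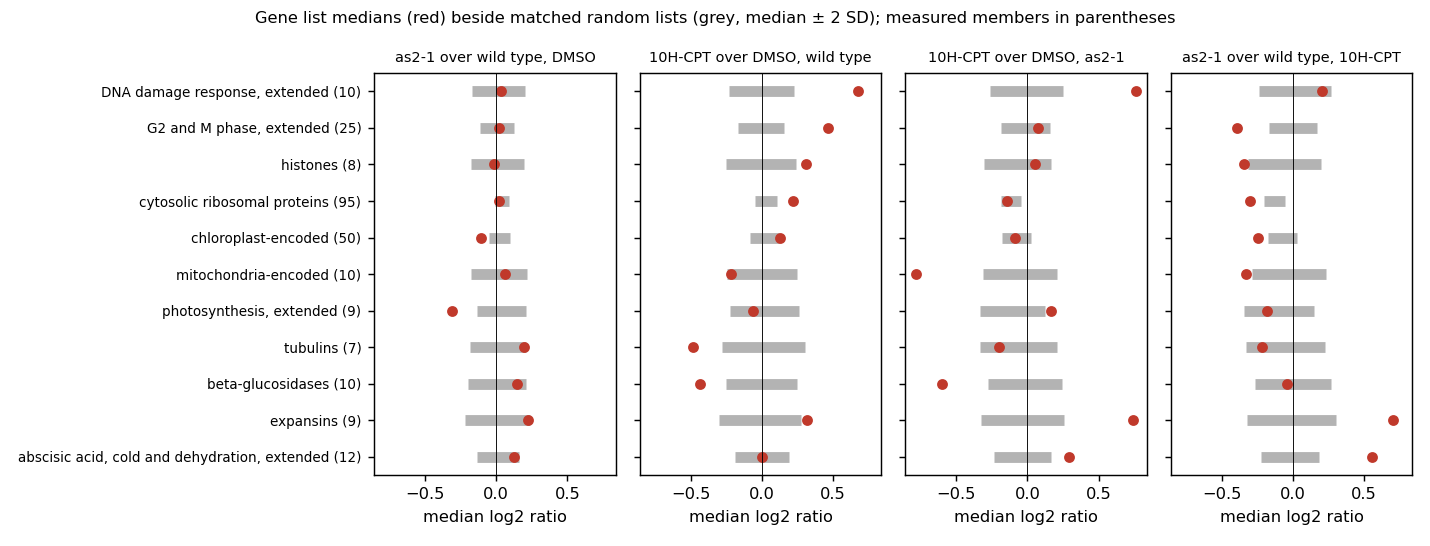
Median log2 ratio (x axis, red points) of 11 gene lists (y axis, measured members in parentheses) in each of the 4 single comparisons, with grey bars for the median of matched random lists ± 2 SD; the lists shown were picked after their values were seen. Ribosomal proteins lie at 0.22 for 10H-CPT in wild type and at -0.15 in as2-1, and expansins at 0.32 and 0.74.

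Expansin genes, which act in cell wall loosening, went both ways on 10H-CPT. Of 9 tested members 3 rose, 1 fell and 5 did not pass limma, with 4 rising and 2 falling when adjusted over the list alone. EXPB3 (AT4G28250) had log2 ratios of 1.58 in wild type and 1.17 in as2-1, EXPA15 (AT2G03090) had 1.202 and 1.14, and EXLA1 (AT3G45970) had -1.38 and -1.66. Beta-glucosidases, 10 measured, had medians of -0.43 and -0.601, at percentiles 0.11 and 0, and 2 of 9 tested fell, BGLU33 (AT2G32860) and BGLU28 (AT2G44460). BGLU33 went from 672 to 285 in wild type and from 708 to 209.9 in as2-1. Tubulin genes, 7 measured, had medians of -0.48 and -0.200, with TUB6 (AT5G12250) at -0.58 and -0.99 and TUB7 (AT2G29550) at 0.57 and 0.042. PDF1.2 (AT5G44420), a defensin gene with 1 array under the floor, rose by 1.66 (SE 0.23, limma adjusted p = 0.0283), and the 5 measured members of the extended defence list had medians of -0.36 and 0, the former 0.289 with the floor at the 60th percentile. UF3GT (AT5G54060), the other measured anthocyanin gene, was higher with 0.55 in wild type and at least 2.503 in as2-1, from under the floor, and passed only when adjusted over the list alone. Of the topoisomerase genes, TOPII (AT3G23890), TOP3A (AT5G63920) and AT2G32000 had wild type ratios of 0.27, 0.51 and -0.44 and as2-1 ratios of 0.13, 0.27 and -0.19, and none passed. Over the 31 tested members of all fixed lists limma called 3 higher and 0 lower on 10H-CPT, and 8 higher and 1 lower when adjusted over the list alone, with all fixed lists as 1 list.

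Other gene groups gave few calls. CML38 (AT1G76650), of 3 tested calmodulin-like genes, fell on 10H-CPT (limma adjusted p = 0.031), to values under the floor in both genotypes. The cyclin-dependent kinase inhibitors SIM, AT1G08180 and AT5G02420 had wild type ratios of -0.403, -0.11 and, ending under the floor, -0.24 or lower. Of these 2 of 3 were lower when adjusted over the list alone, as were both tested auxin genes, GH3.3 at -0.35 and WES1 at -0.47. Median 10H-CPT ratios in wild type and as2-1 were -0.081 and -0.062 for 22 UDP-glycosyltransferases, -0.25 and -0.068 for 9 bZIP factors, -0.19 and 0.16 for 8 cytochromes P450 of the 71B group, and 0.0095 and 0.36 for 6 glutathione S-transferases of the tau class. For 4 members each they were 0.25 and 0.41 for SWEET sugar transporters, -0.090 and -0.34 for xyloglucan endotransglucosylases, and -0.19 and -0.020 for AGAMOUS-like factors. The as2-1 medians changed sign for UDP-glycosyltransferases with the floor at the 60th percentile, to 0.0861, and for cytochromes P450 without a floor, to -0.0663. The extended xenobiotic list, 5 measured, had medians of -0.32 and 0, and no member of these groups of enzymes, transporters and factors passed limma for either mean effect. No named gene of the heat shock, meristem, root, stomatal and trichome lists was above the floor.

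Loss of AS2 function went with lower transcripts of genes that included EXO, AT3G15450 and AT5G61590 on both media, and with higher transcripts of QQS and APL3. QQS (AT3G30720), an orphan gene known to affect starch content, had signals of 34.7 and 454 on DMSO, at least 9.74-fold higher in as2-1, and of 62.5 and 385 on 10H-CPT. It rose by a mean log2 ratio of 2.95 with its floored value (SE 0.21, limma adjusted p = 0.0386). EXO (AT4G08950), a brassinosteroid-responsive gene of cell expansion, fell, with a mean log2 ratio of -1.696 (SE 0.17, limma adjusted p = 0.0418), from 437 to 140.4 on DMSO and from 269.9 to 80.0 on 10H-CPT. The limma test of the mean as2-1 effect called 7 probe sets higher and 16 lower, of which 12 have 1 named gene, and at an unadjusted p under 0.05 it gave 972 higher and 788 lower. Without the floor limma called 0 either way (860 higher and 651 lower unadjusted), and 0 also with all probe sets tested (867 and 893), while over the other settings it called up to 39 higher and up to 53 lower.

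In single comparisons as2-1 had 146 probe sets at or over 2-fold higher and 155 lower than wild type on DMSO, and 382 higher and 222 lower on 10H-CPT. On DMSO higher probe sets outnumbered lower ones without the floor (1917 to 1521), at 3-fold (36 to 35) and at 1.5-fold (635 to 603). Of the named genes above the floor in all arrays, 16 were higher and 17 lower on both media. The lowest was AT5G61590, which fell, with a mean log2 ratio of -2.22 (SE 0.21, limma adjusted p = 0.0386), with 675 and 179 on DMSO. AT3G15450 stood at 2974 and 757 on DMSO and at 1650.0 and 442 on 10H-CPT, a mean log2 ratio of -1.94 (SE 0.17, limma adjusted p = 0.0386). AT5G44020, AT5G14120, AT1G23390, AT2G30930 and AT4G21870 also fell, with mean log2 ratios of -1.93, -1.67, -1.63, -1.72 and -1.51. AT5G19120 and AT2G45180 were lower by 2.48-fold and 2.44-fold on DMSO, each at a limma adjusted p of 0.0528. None of the 10 highest passed limma. APL3 (AT4G39210), a subunit of the starch synthesis enzyme ADP-glucose pyrophosphorylase, had 55.6 and 170.5 on DMSO and 57.4 and 333 on 10H-CPT (limma adjusted p = 0.0528). The endoglucanase-family genes GH9C2 (AT1G64390) and GH9B8 (AT2G32990) were 2.49-fold and 2.31-fold higher on DMSO, and MT1C (AT1G07610), a metallothionein, was 2.20-fold higher. AT2G41190, AT3G02500, AT5G59480, AT5G19875, AT1G73390 and BETA-VPE (AT1G62710), a vacuolar processing enzyme, were between 2.13-fold and 3.04-fold higher on DMSO.

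On DMSO, BCAT4 was 5.52-fold higher in as2-1, AT2G31790 was 2.81-fold higher and GSTU20 (AT1G78370), a glutathione S-transferase, was 2.80-fold higher. AT2G20670 and MSRB9 (AT4G21850), a methionine sulfoxide reductase, were 4.57-fold and 4.46-fold lower, and on 10H-CPT 2.18-fold and 2.099-fold lower. AT4G10910, AT2G41730 and AT4G16260 lay under the floor in as2-1 and were at least 3.80-fold, 3.17-fold and 3.01-fold lower. On 10H-CPT, PUB19 (AT1G60190), a ubiquitin ligase of abscisic acid and drought responses, had 566 in as2-1 and 4.30 in wild type, at least 12.2-fold. AT1G20070, AT2G47780, AT4G35720 and AT1G80130 were 9.74-fold, 9.63-fold, 8.44-fold and 7.08-fold higher in as2-1, and AT5G53710 and AT4G28140 at least 5.77-fold and 5.53-fold higher. GH3.3 (AT2G23170), an auxin-conjugating enzyme, was 4.50-fold lower in as2-1 on 10H-CPT, as were AT2G10940, AT4G16980 and AT1G29270 by 4.78-fold, 4.69-fold and 4.28-fold. AT1G23130, AT3G49790 and EXPA8 (AT2G40610) were at least 3.88-fold, 3.41-fold and 3.23-fold lower.

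Among leaf polarity genes, YAB5 (AT2G26580), a gene of abaxial identity, had as2-1 over wild type log2 ratios of 0.84 on DMSO and 0.86 on 10H-CPT, and YAB3 (AT4G00180) had -0.497 and -0.077. PHV (AT1G30490), a gene of adaxial identity, had -0.14 and -0.65. None of these passed limma over all probe sets, and YAB5 passed when adjusted over its list alone, which had 2 tested members. ARR15 (AT1G74890), a cytokinin response regulator, was higher by at least 0.76 and at least 0.47, from under the floor, without passing over all probe sets. It was the only tested member of its list, so its pass over the list alone is an unadjusted limma p under 0.05. Of 13924 probe sets, 972 higher and 788 lower met that bound for the mean as2-1 effect. SIM (AT5G04470), an inhibitor of cyclin-dependent kinases, had 0.36 and 0.026. The auxin-conjugating genes GH3.3 and WES1 (AT4G27260) had as2-1 ratios of -0.32 and 0.0017 on DMSO and of -2.17 and -0.57 on 10H-CPT. DME (AT5G04560), a DNA demethylase, had 0.198 and -0.090. Photosynthesis genes were lower in as2-1 on DMSO, with a median of -0.31 at percentile 0.035 and 7 of 9 members below 0, and had a median of -0.18 on 10H-CPT. Genes of abscisic acid, cold and dehydration were higher in as2-1 on 10H-CPT, where the 12 measured members had a median of 0.56 at percentile 99.99, against 0.13 on DMSO. COR47 (AT1G20440), a dehydrin, stood at 425 and 1460.4 on 10H-CPT, and none of the 9 tested members passed limma, with 3 higher when adjusted over the list alone. Expansins had medians of 0.22 and 0.703, with 1 fall by limma, EXLB1 (AT4G17030), whose log2 ratios were -1.58 on DMSO and -1.46 or lower on 10H-CPT, and 4 rose and 2 fell when adjusted over the list alone. Ribosomal protein and G2 and M phase genes had medians of 0.018 and 0.019 on DMSO, the former turning sign with scaling, and of -0.31 and -0.39 on 10H-CPT. On 10H-CPT the ribosomal protein median lay below that of matched random lists under the deposited scaling (random median -0.13) and with loess scaling (-0.184 beside -0.0284), at percentile 0 in both. Over the 31 tested members of all fixed lists limma called 0 higher and 0 lower in as2-1, and likewise when adjusted over the list alone, with all fixed lists as 1 list.

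**Figure D3:**
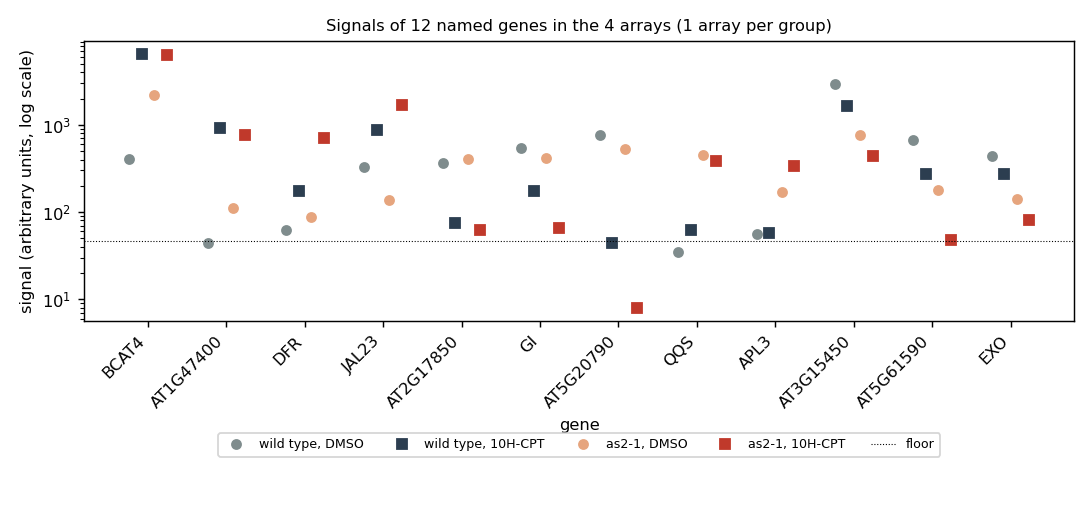
Signal (y axis, arbitrary units, log scale) of 12 named genes (x axis) in wild type on DMSO, wild type on 10H-CPT, as2-1 on DMSO and as2-1 on 10H-CPT, with 1 point per array and a dotted line at the floor of 46.6; the genes shown were picked after their values were seen. AT3G15450 lies at 2974 and 1650.0 in wild type and at 757 and 442 in as2-1.

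Both factors together gave the most differences, with 609 probe sets at or over 2-fold higher and 503 lower in as2-1 on 10H-CPT than in wild type on DMSO. The genotypes differed by at least 2-fold in their 10H-CPT ratio at 272 probe sets higher and 158 lower in as2-1, of 12716 above the floor in all arrays, and this difference was not tested. Without the floor the counts were 1776 and 1793. Of named genes above the floor in all arrays BCAT4 had the lowest difference, -2.496. It was followed by GH3.3, AT3G56360, AT2G30540 and AT2G10940 with -1.85, -1.74, -1.74 and -1.74. AT3G56360 stood at 1509 and 1239 in wild type and as2-1 on 10H-CPT and at 211 and 580.1 on DMSO, whereas GH3.3 went from 430.5 to 93.7 in as2-1 and from 537 to 421 in wild type. Of named genes above the floor in all arrays JAL23 had the highest difference, 2.198, and AT1G80130, AT1G21000, AT1G68500 and AT1G43910 had 2.195, 2.18, 2.13 and 2.08. AT3G28220 was at least 10.7-fold higher on 10H-CPT in as2-1 and at least 2.29-fold higher in wild type. The anthocyanin gene DFR had a difference of 1.48, and COR15A (AT2G42540), a cold-regulated gene, had 10H-CPT ratios of -1.25 or lower in wild type, ending under the floor, and 0.67 in as2-1. Of lists written before values were seen, with at least 5 measured members, those below percentile 2 of matched random lists were mitochondria-encoded transcripts with a median difference of -0.53, G2 and M phase genes with -0.42, beta-glucosidases with -0.401, tubulins with -0.38, ribosomal proteins with -0.35 and chloroplast-encoded transcripts with -0.25. Those above percentile 98 were the extended xenobiotic list with 0.85, cytochromes P450 of the 71B group with 0.37, genes of abscisic acid, cold and dehydration with 0.32 and photosynthesis genes with 0.22. For tubulins the median of the members' differences was negative, although their median 10H-CPT ratio was lower in wild type than in as2-1. The direction for this list thus depends on the summary used. List differences did not require all arrays above the floor. Of the 5 measured members of the xenobiotic list 3 lay above the floor in at least 2 arrays, so floored values enter its difference. Matched random lists had medians of -0.14 for ribosomal proteins and -0.102 for chloroplast-encoded transcripts under the deposited scaling. With quantile and loess scaling ribosomal proteins had -0.2097 and -0.2068 beside random medians of -0.0663 and -0.044, at percentiles 0.01 and 0. Chloroplast-encoded transcripts had -0.0909 and -0.0932 beside -0.0513 and -0.0327, at percentiles 21.45 and 9.69, and so were no longer below percentile 2. With the floor at the 60th percentile beta-glucosidases had -0.157, cytochromes P450 0.206 and genes of abscisic acid, cold and dehydration 0.118.

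The 10H-CPT ratios of the genotypes, which share no array, correlated across 12716 probe sets with Pearson's r of 0.489 and Spearman's rho of 0.392, and without the floor r was 0.214. At 2-fold, 89 probe sets were higher in both genotypes where independent lists would share 4.53, 90 were lower in both against 3.95, and 3 went opposite ways. The as2-1 ratios on both media correlated with r of 0.375 and rho of 0.306 (r of 0.111 without the floor), with 34 higher on both against 2.55 and 51 lower on both against 1.59. The mean as2-1 effect and the mean 10H-CPT effect had r of 0.254 and rho of 0.107, and r of 0.119 without the floor. Both are computed from the same 4 arrays, where noise in as2-1 on 10H-CPT or wild type on DMSO adds to a positive r, noise in the other arrays adds to a negative r, and equal noise in all gives an r of 0. Of probe sets with mean effects at or over 2-fold, 39 were higher in both where independent lists would share 1.68, 22 were lower in both against 1.15, and 2 went opposite ways, but with 1 array per group unequal noise was not measured. AT5G61590 fell in both mean effects by limma, and EXPB3 and EXPA15 rose on 10H-CPT and were higher in as2-1 by log2 ratios of 1.43 and 1.105 on DMSO.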

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

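All tests in this part were chosen after the results were seen, and the differences between groups given here were not tested because each group has 1 array. In wild type and as2-1 the 10H-CPT ratio went opposite ways, by at least 2-fold each, at 3 probe sets that have no gene named in the annotation used here. The log2 ratios were -1.71 in wild type and 1.57 in as2-1 for the first, -1.82 and 1.21 for the second, and -1.26 and 4.02 for the third. The as2-1 ratio went opposite ways on DMSO and 10H-CPT at 4 unnamed probe sets, with -1.29 and 1.75 for the second of these 3, -1.77 and 3.51 for the third, and -1.58 and 2.12 and then -1.27 and 2.26 for the remaining pair. Signals of the third were 270.5 and 113 in wild type and 79.4 and 1284.5 in as2-1, on DMSO and 10H-CPT.

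Genes of cytosolic ribosomal proteins had a median 10H-CPT log2 ratio of 0.22 in wild type and -0.15 in as2-1, and stood out among lists of at least 10 members for medians of opposite sign, both over 2 SD of random medians from 0. Matched random lists had -0.11 in as2-1, and with loess scaling the as2-1 median was -0.034 beside -0.0282, so the negative sign there does not set this list apart. The list thresholds were set after values were seen. The genotype difference of ribosomal proteins depended in part on scaling between arrays. It went from -0.35 (matched random lists -0.14) to -0.2097 with quantile and -0.2068 with loess scaling (random -0.0663 and -0.044). With medians set equal it stayed at -0.3456 (random -0.1429). Setting medians equal shifts each array by a constant, so it could not change how far a list lies from random lists. Quantile and loess scaling did not remove all of the difference. Under both, this list and the G2 and M phase list stayed over 2 SD below matched random lists. The nearest lay -0.143 from the random median (SD 0.035). That SD comes from genes drawn independently and may be too small for lists whose members vary together. A first version of this test measured from 0 and not from random lists. The wild type 10H-CPT array alone may be the source, since in the as2-1 pair, which does not use it, the ribosomal protein median lay at percentile 23.5 of matched random lists, as a response of wild type alone would give. A larger share of dividing tissue in that sample stays open, since photosynthesis genes lay at percentile 25.4 in the wild type pair, and so does a difference in response between genotypes, which was not tested.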

How the results depend on the processing

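All alternatives were fixed before the data were examined. No correlation, no ratio at or over 2-fold of the named or listed genes and no list median over 2 SD of random medians from 0 changed sign under the alternatives. Ratios of other probe sets were not followed. The larger of the higher and lower counts changed without a floor for as2-1 on DMSO, 10H-CPT in as2-1 and the genotype difference, and at 3-fold and 1.5-fold for as2-1 on DMSO. It also changed for the limma calls of the mean 10H-CPT effect with the floor at the 60th percentile, and for the unadjusted calls of the mean as2-1 effect with equal medians (870 higher and 887 lower) and with all probe sets tested. Of all counts, 63 of 144 were within 1.5 times the reported count, and 81 were not. Of 11516 ratios of named or listed genes, 427 moved by more than the SD of that ratio over 500 probe sets of similar mean signal. Of 920 list medians, 95 moved by more than the SD of random medians, and 3 of 21 correlations moved by more than 0.1. No paired analysis was possible because each group has 1 array and no replicate numbers pair samples, although the additive model takes each effect within the other factor. Except where the setting itself changes the threshold or the number of probe sets tested, the cause was not tested.

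Without a floor the counts were 1917 higher and 1521 lower for as2-1 on DMSO, 1837 higher and 1996 lower for 10H-CPT in wild type, 1924 higher and 2152 lower for 10H-CPT in as2-1. They were 2039 higher and 1719 lower for as2-1 on 10H-CPT, 2364 higher and 2163 lower for both factors, 1776 higher and 1793 lower for the genotype difference in this setting. With the floor at the 60th percentile the counts were 77 higher and 82 lower for as2-1 on DMSO, 120 higher and 135 lower for 10H-CPT in wild type, 235 higher and 151 lower for 10H-CPT in as2-1. They were 196 higher and 104 lower for as2-1 on 10H-CPT, 344 higher and 266 lower for both factors, 107 higher and 73 lower for the genotype difference in this setting. With the floor as a pseudocount the counts were 76 higher and 86 lower for as2-1 on DMSO, 141 higher and 181 lower for 10H-CPT in wild type, 195 lower for 10H-CPT in as2-1. They were 246 higher and 116 lower for as2-1 on 10H-CPT, 158 higher and 79 lower for the genotype difference in this setting. At 3-fold the counts were 36 higher and 35 lower for as2-1 on DMSO, 68 higher and 84 lower for 10H-CPT in wild type, 133 higher and 94 lower for 10H-CPT in as2-1. At this threshold they were 125 higher and 54 lower for as2-1 on 10H-CPT, 248 higher and 195 lower for both factors, 73 higher and 34 lower for the genotype difference. At 1.5-fold the counts were 635 higher and 603 lower for as2-1 on DMSO, 852 higher and 1037 lower for 10H-CPT in wild type, 1122 higher and 1074 lower for 10H-CPT in as2-1. They were 1175 higher and 945 lower for as2-1 on 10H-CPT, 1438 higher and 1396 lower for both factors, 1006 higher and 936 lower for the genotype difference in this setting. For the mean 10H-CPT effect limma called 0 higher and 0 lower without a floor (899 and 1095 at an unadjusted p under 0.05) and 0 and 0 with all probe sets tested (979 and 1216). It called 93 higher and 92 lower with the floor at the 60th percentile, 232 higher and 292 lower with the floor as a pseudocount, and 210 higher with an intensity trend. For the mean as2-1 effect limma called 0 higher and 0 lower without a floor (860 and 651 unadjusted) and 0 and 0 with all probe sets tested (867 and 893). It called 4 higher and 8 lower with the floor at the 60th percentile, 36 and 53 with a pseudocount, 12 and 27 with quantile scaling, 15 and 28 with loess scaling, 15 and 29 without probe sets ending in _s_at or _x_at, and 39 and 52 with an intensity trend. Without a floor Pearson's r was 0.214 for the 10H-CPT ratios of both genotypes, 0.111 for the as2-1 ratios on both media and 0.119 for the mean effects. The median of the extended DNA damage list was 1.06 in wild type and 1.24 in as2-1 without a floor, 0.154 and 0.491 with the floor at the 60th percentile, and 0.548 in wild type with a pseudocount. The median of the extended G2 and M phase list was 0.573 for 10H-CPT in wild type without a floor and -0.267 for as2-1 on 10H-CPT with a pseudocount. For ribosomal proteins quantile and loess scaling gave 0.1797 and 0.1808 for 10H-CPT in wild type, -0.0626 and -0.0337 in as2-1, -0.219 and -0.184 for as2-1 on 10H-CPT, and -0.2097 and -0.207 for the genotype difference. Medians near 0 for as2-1 on DMSO turned sign with scaling for ribosomal proteins, bZIP factors, hypoxia genes and genes of the nucleolus.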

Other observations

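All lists, tests and thresholds in this part were chosen after results had been seen. The 7 lists drew their members from background knowledge once the strongest genes were known, and values of many members of the hypoxia, glucosinolate, sugar, circadian and sulfur lists had been seen by then, but not those of the iron and phosphate genes that did not prompt their lists. Lists of this kind are prompted by some of their own members, so medians are also given for the other members. GSTU20, CML38, BGLU28, AT1G33055 and AT4G33560 also stand in other groups described here.

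Genes that hypoxia induces were lower on 10H-CPT in both genotypes. The 24 measured members had median log2 ratios of -1.21 in wild type and -1.33 in as2-1, and the 18 members other than those that prompted the list had -1.004 and -1.08, both at percentile 0 of matched random lists. AT1G19530 went from 334 to 69.9 in wild type, AT3G10040 from 199.8 to 63.5, and PDC2 (AT5G54960), a pyruvate decarboxylase, from 538 to 359, while AT1G72940 was higher with 0.57. The 4 measured genes of phosphate starvation were all at or over 2-fold lower in both genotypes, with medians of -2.18 and -1.73, and the 2 that did not prompt the list, AT1G23140 and AT1G67600, had bounds of -2.05 and -2.08 in wild type. Genes of iron deficiency had medians of 0.899 in wild type and 0.54 in as2-1 over 8 members. Over the 5 others the medians were 0.54 and 0.15, at percentiles 99.65 and 75.385 of matched random lists. The others thus lay near the top of random lists in wild type and within them in as2-1, but the genotype difference was not tested. PYE (AT3G47640), a regulator of iron homeostasis, had 1.22 and 0.69. The circadian list, 6 measured, also held FHL, described above as acting in phytochrome A signalling. The list had medians of -0.93 and -0.63 on 10H-CPT, and of -0.42 and -0.21 over the 4 other than GI and FHL. Both measured genes of sulfur deficiency, AT1G04770 and BGLU28, were lower on 10H-CPT, with a median of -1.03 in wild type and -1.75 in as2-1. Genes of sugar starvation, 10 measured, had a median as2-1 log2 ratio of -0.99 on DMSO and -0.82 on 10H-CPT, and the 5 other members had -0.47 on DMSO and, opposite to the whole list, 0.41 on 10H-CPT.

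For the hypoxia genes, scaling between arrays does not account for the lower values, because the median of the other members stayed at or below -0.97 in both genotypes under 3 other scalings. A single atypical array cannot by itself lower these members in both drug pairs, since the pairs share no array and the median nearer to 0 was -1.004. Values of many of these members had been seen when the list was written, so low medians in both pairs were partly set by that choice. Growth or harvest of the 10H-CPT plates, such as time of day or air supply, could give the same pattern and cannot be told apart from the drug, as medium and plate coincide; on DMSO the genotypes differed by a median of 0.023 in these members, and for the whole list the sign of this median turned with scaling.

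Genes of aliphatic glucosinolate synthesis, 6 measured, were lowest in wild type on DMSO, with a median of 1.38 for as2-1 over wild type on DMSO, 2.48 and 1.37 for 10H-CPT in wild type and as2-1, and 0.065 for as2-1 over wild type on 10H-CPT. Of the 6, 4 were picked because they were high on 10H-CPT in both genotypes. GSTU20 had also been seen by then, among the highest named genes for 10H-CPT in wild type and for as2-1 on DMSO. Only UGT74B1 (AT1G24100) is left to bear on whether the wild type DMSO array alone could give the pattern. In as2-1, which does not use that array, GSTU20 and UGT74B1 had 10H-CPT ratios of 1.02 and 0.58. The ratio of UGT74B1 exceeds the bound of 0.5 by less than the SD of 0.48 of all such ratios. A role of that array alone thus stays open, as does an effect of as2-1 on DMSO, which was not tested. A version of the test over all 6 members, also tried after values were seen, gave a median of 1.37 and was not used, because 4 of the members had prompted the list. Saturation of signals on 10H-CPT could also hide a genotype difference, and the 2 members far under the highest signal differed there by a median of 0.12, which is too few members to decide.

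Of 33 named genes that differed by at least 2-fold the same way in as2-1 on both media, 3 lie within 500 genes of the AS2 locus (9.09%), where 189 of the 6819 probe sets compared (2.77%) lie. The 3 are GH9C2, BETA-VPE and AT1G64620, all higher in as2-1 and named here after their values were seen; no test was made, and sequence differences linked to the mutation were not analysed here.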
